A study of Rattus norvegicus with 36 samples.

How the data were processed

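Gene expression was measured in mammary glands of rats from the strains Cop (Copenhagen) and F344 (Fischer), treated at 55 days of age with N-nitrosomethylurea (NMU) or with saline vehicle. Glands were collected 6 h, 1 d or 30 d later. The 36 arrays fall into 12 groups of 3, formed by 2 strains, 2 treatments and 3 times, and no array was left out. The labels call the replicates biological and say nothing more about them, and whether each array is a separate animal is not stated. The p-values measure the spread between replicate arrays pooled over all 12 groups, not the spread of the compared arrays alone. F344 control replicates 1 and 2 at 1 d were the closest of all replicate pairs (root mean square log2 difference 0.163, next 0.232), which leaves open whether they are separate animals. The dose of NMU, the time of day of collection and any processing batch are not given in the sources used here.

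Per the labels, RNA was prepared with Qiagen RNeasy Maxi columns, and biotin-labelled cRNA was made from 1 ug of total RNA by the standard Affymetrix procedure. The submitters' notes name GCOS as processing software, without a version. How the probe signals were summarized and normalized is not given in the sources used here. The deposited values are the authors' expression values per probe set on a log2 scale, between 2.46 and 14.3 over all arrays. Array medians lay between 5.66 and 5.77, a range of 0.110, so the deposited values were taken as already normalized between arrays and used without a further step. Arrays have no read depth, and the number of arrays limits the precision.

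The deposited table holds 31099 probe sets. By the annotation used here, 20832 of them carry 1 gene symbol, 436 carry several, and 9831 have no name. Of those with 1 symbol, 68 have an Entrez identifier that the gene table lacks. The files name no genome build, so no coordinates are given. A probe set was tested if it lay above the 40th percentile of its own array on at least 3 arrays. This kept 20748 probe sets and left out 10294, besides 57 control probe sets of the manufacturer. For gene lists and gene counts, each of 11509 genes was represented by its probe set of highest mean.

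A linear model with a mean for each of the 12 groups was fitted to all 36 arrays with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes moderation. Tests were two-sided moderated tests, adjusted by Benjamini-Hochberg within each of the 12 comparisons, and a probe set was called at an adjusted p under 0.05. The comparisons are NMU against control within each strain and time, the strain difference in that response at each time (Cop response minus F344 response), Cop against F344 over the controls, and 1 d against 6 h, and 30 d against both earlier times, over the controls of both strains. Genes called in both strains were compared with the number expected from independent draws by Fisher's exact test.

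Before the data were examined, 34 lists of pathway genes and cell type markers were fixed, with 794 entries of which 697 matched a measured gene. Also fixed then were the comparisons, the threshold, the filter, most alternatives, and the rule for naming genes. Lists were tested against all other genes with camera at a preset correlation between genes of 0.01, adjusted over all lists and comparisons. Camera was run again with the correlation estimated from the data, and 5 of the 173 list calls held then. A list's count is given over all probe sets tested and, where it differs, adjusted over the list alone. A list score of an array is the mean, over the list's genes, of the deviation from each gene's mean log2 value.

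Genes were named by this rule: among called probe sets with a unique symbol, where every array of an arm lay above every array of the other, the 10 largest rises and 10 largest falls. For Cop against F344 this condition was asked within each time, and for the comparisons of times within each strain. For the strain difference in response the rule took 5 of each and had no condition on single arrays. The rule added up to 4 members of smallest p from each list called or holding at least 3 called members. Where nothing passed, it took the 3 genes of smallest p in each direction. Prlr, Per2, Cdkn1a and Mgmt were examined in every NMU comparison. The text prints a part of the genes this rule gives.

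Alternatives fixed before the data were examined were quantile normalization, a floor at the 20th percentile, no filter on dim probe sets, a filter at the 60th percentile, empirical Bayes without trend and robust options, the replicate number as a block, a model of the compared arrays alone, leaving out each array in turn, and, for lists, an estimated correlation or the mean of a gene's probe sets. Replicate numbers come from the labels, which give them no meaning. Arrays of the same number deviated together in Cop at 6 h (correlations 0.114, 0.142 and 0.435) and in Cop at 1 d (0.202, 0.424 and 0.315), so a model with these pairs as a block was added. Also added after seeing the data were the skeletal muscle score as a covariate, the mean of the T cell and B cell scores as a covariate, the closest pair of replicates averaged, and Cop at 30 d without the 2 NMU arrays of highest GAPDH 3 prime to 5 prime difference, which left 1 NMU array. The model was also tested on simulated data with 200 of 20748 probe sets changed. For a single strain and time it recovered 90.0% of changes of 1 log2 unit and 98.0% of changes of 2, with 10 false calls. For the strain difference in response it recovered 55.0% and 93.0%, with 8 false calls. The simulated noise was drawn for each probe set on its own, with the same spread in every group. Real genes vary together and the groups differ in spread, so these numbers do not give the false calls on the real arrays.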

Results

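Expression was measured on Affymetrix rat arrays in mammary glands of Cop and F344 rats, with 18 arrays per strain. NMU is an alkylating agent that methylates DNA and induces mammary tumours in susceptible rats. F344 is susceptible to this carcinogen and Cop is resistant. Each strain gave 3 arrays per treatment at 6 h, 1 d and 30 d. Skeletal muscle markers varied widely between single glands. The score of 26 such genes ranged from -3.58 in F344 control replicate 1 at 30 d to 2.67 in F344 control replicate 3 at 6 h. With no marker passing, the list was called lower in F344 at 6 h (median -0.17, adjusted p = 0.0329, and adjusted p = 0.792 with an estimated correlation) and higher in Cop at 1 d (median 0.95, adjusted p = 0.00677, and adjusted p = 0.741 with an estimated correlation).

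**Figure D1:**
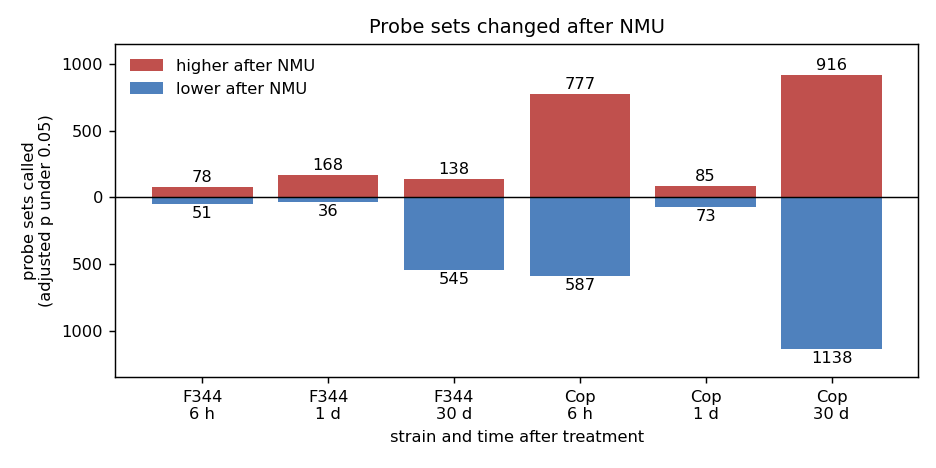
Number of probe sets called (limma adjusted p under 0.05) as higher (upward bars) or lower (downward bars) after NMU, by strain and time, with 3 NMU and 3 control arrays per comparison. The bars run from 36 lower in F344 at 1 d to 1138 lower in Cop at 30 d.

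In F344 at 6 h, the neutrophil calcium-binding proteins rose. S100a9 went from 5.13 ± 0.392 in controls (mean log2 value ± SD, n = 3) to 7.49 ± 0.13 after NMU (n = 3), a rise of 2.36 (SE 0.352, limma adjusted p = 0.00141), and S100a8 rose by 2.04. Sele, an adhesion molecule of activated endothelium, rose by 1.51, the matrix protease Mmp12 by 1.76 and the stress gene Nupr1 by 1.08. Of 29 measured p53 targets, 3 rose, and 8 did so adjusted over the list alone: the cell cycle inhibitor Cdkn1a by 1.46 (SE 0.259, adjusted p = 0.0066), the nuclease Aen by 0.94 and the death receptor Fas by 0.90. The list was called higher (camera adjusted p = 0.000307, and adjusted p = 0.369 with an estimated correlation). Of 23 genes of fatty acid and sterol synthesis, 3 fell, and 15 did so adjusted over the list alone: Insig1 with a log2 change of -1.69 (SE 0.264, adjusted p = 0.00167), Nsdhl with -1.04 and Cyp51 with -0.66. This list was called lower (adjusted p = 5.75e-21, and adjusted p = 0.0834 with an estimated correlation). The lipid droplet gene Pnpla3, outside that list, fell with -2.79. Of 26 fibroblast and matrix genes, 2 fell, Fn1 with -0.74 and Fbn1 with -0.67 (7 adjusted over the list alone; list adjusted p = 1.13e-07, and adjusted p = 0.419 with an estimated correlation).

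In this comparison 129 probe sets were called, 78 higher and 51 lower, which read 85 genes. Quantile normalization gave 62 higher and 84 lower, so the balance of directions turned with the scaling, while no named gene reversed. The count was 7 with the compared arrays alone, 85 without the filter, 342 with the lymphocyte score as a covariate, and 70, 24, 42, 51 and 23 without F344 control replicate 1, 2 or 3 or NMU replicate 1 or 2 in turn. S100a8, S100a9, Sele, Nupr1, Insig1 and Nsdhl passed whichever array was left out, Cdkn1a lost its call without control replicate 2, and the other genes named lost theirs without at least 1 array.

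In F344 at 1 d, interferon-stimulated genes dominated the response. Of 26 measured members, 25 rose and none fell (camera adjusted p = 1.4e-84, and adjusted p = 0.000144 with an estimated correlation). The T cell attracting chemokine Cxcl11 went from 4.65 ± 0.115 (SD, n = 3) to 9.87 ± 0.0757 (n = 3), a rise of 5.22 (SE 0.285, limma adjusted p = 3.72e-13). Cxcl10 went from 6.18 ± 0.209 to 9.78 ± 0.145 (SD, n = 3 each). Cxcl9 rose by 2.23, the antiviral genes Mx1 by 2.98 and Isg15 by 2.39, the transcription factor Irf7 by 2.34 and the GTPase Gbp2 by 1.67. Of 17 genes of the rat major histocompatibility complex and its light chain, 4 rose (6 adjusted over the list alone), among them RT1-S3 by 1.31, RT1-N3 by 1.17 and B2m by 0.32. Of 20 T and NK cell markers, 3 rose: the cytotoxic granule genes Gzmb by 2.44, Nkg7 by 1.58 and Gzma by 1.29. Of 23 inflammatory genes, 3 rose (6 adjusted over the list alone), among them the monocyte attractant Ccl7 by 1.81, and outside the lists the lymphoid chemokine Ccl19 rose by 3.12. The last 3 lists were called higher at camera adjusted p = 3.61e-10, 0.00216 and 6.19e-08, and none held with an estimated correlation, where the adjusted p were 0.258, 0.672 and 0.258. The beta globin gene Hbb fell with a log2 change of -2.26.

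The comparison called 204 probe sets, 168 higher and 36 lower. Every gene named in the paragraph before passed whichever array was left out. Other genes that the naming rule gave did not, among them Ccl4 and Gpc6, which each lost the call without any 1 of the 6 arrays. The skeletal muscle score was -2.15 in NMU replicate 1 against 2.34 and 1.17 in the other NMU arrays, and no muscle marker passed (list median -1.94, called lower at adjusted p = 1.43e-07, and adjusted p = 0.55 with an estimated correlation).

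In F344 at 30 d, genes of cell division were lower after NMU. Of 38 genes of the G2 and M phases, 28 fell, and 38 did so adjusted over the list alone (median log2 change -1.42, camera adjusted p = 3.03e-26, and adjusted p = 0.258 with an estimated correlation). Cyclin A2, Ccna2, went from 6.21 ± 1.36 (SD, n = 3) to 3.81 ± 0.441 (n = 3), a change of -2.41 (SE 0.435, limma adjusted p = 0.00428), and the topoisomerase Top2a changed by -1.85. Of 28 S phase genes, 17 fell (21 adjusted over the list alone), among them the DNA clamp Pcna with -0.97 and the replicative helicase subunit Mcm6 with -1.34 (list adjusted p = 2.48e-15, and adjusted p = 0.286 with an estimated correlation). The phosphate transporter Slc34a2 fell with -3.32, the fatty acid binding protein Fabp3 with -2.85 and the carbonic anhydrase Car2 with -2.74. The transferrin receptor Tfrc fell with -1.66 (SE 0.239, adjusted p = 0.000586). Of 15 genes of alkylation and base excision repair, 2 fell (5 adjusted over the list alone), Apex1 with -0.67 and Fen1 with -0.73 (list adjusted p = 0.00613, and adjusted p = 0.371 with an estimated correlation). The Wnt antagonist Sfrp4 rose by 1.36 and the lipid droplet coat gene Plin1 by 0.90. Of 26 fibroblast and matrix genes 3 rose, among them elastin, Eln, by 0.85, and of 14 endothelial genes 3 rose, among them Tek by 0.66 and Pecam1 by 0.64. Adjusted over the list alone, these counts were 13 and 10, and the lists were called higher at adjusted p = 3.04e-10 and 2.79e-09, with adjusted p of 0.369 and 0.181 with an estimated correlation.

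The G2/M score of control replicate 2 was -0.116, inside the range of the NMU arrays (-0.573, -0.023 and -0.413), and the fall rested on control replicates 1 and 3 (1.97 and 1.43). This comparison called 683 probe sets, 138 higher and 545 lower, against 286 higher and 563 lower after quantile normalization. The skeletal muscle score moved with the arms, at -2.29 ± 1.60 (SD, n = 3) in controls and 0.625 ± 0.924 (n = 3) after NMU, and it was lowest in the 2 control arrays with the highest G2/M scores (-3.58 and -2.80). No muscle marker passed, 17 of 26 were higher adjusted over the list alone, and the list was called higher (median 3.49, adjusted p = 1.83e-12, and adjusted p = 0.419 with an estimated correlation). With that score as a covariate 13 probe sets were called, while the G2/M median went from -1.42 to -1.19 and 100% of the called changes kept their sign. With the compared arrays alone the count was 2, and without each array in turn 29, 1109 and 196 (control replicates 1, 2 and 3) or 38, 166 and 1101 (NMU replicates 1, 2 and 3). Sfrp4, Slc34a2, Tfrc and Pcna passed whichever array was left out, and the other genes named lost their calls without at least 1 array.

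In Cop at 6 h, genes of fatty acid and sterol synthesis fell together. Of 23 measured members, 21 fell (22 adjusted over the list alone; camera adjusted p = 4.47e-28, and adjusted p = 0.0417 with an estimated correlation). Fatty acid synthase, Fasn, went from 12.37 ± 0.024 (SD, n = 3) to 10.41 ± 0.119 (n = 3), a change of -1.96 (SE 0.206, limma adjusted p = 7.81e-07). Acaca, the rate-limiting enzyme of fatty acid synthesis, changed by -2.06, Acly by -1.84 and the regulator Srebf1 by -1.23. Angptl8, an inhibitor of lipoprotein lipase activity, fell with -4.36 (SE 0.562, adjusted p = 1.94e-05). Angptl4 rose by 2.92 and Pdk4, which restrains glucose oxidation, by 3.59. Of 23 adipocyte genes 9 fell (11 adjusted over the list alone), among them Dgat2 with -1.79 and Gpd1 with -1.45 (list adjusted p = 1.18e-07, and adjusted p = 0.369 with an estimated correlation).

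Fibroblast and matrix genes rose at the same time in Cop. Of 26 members 19 rose, among them the collagen crosslinking enzyme Lox by 2.54 (SE 0.267, limma adjusted p = 7.81e-07), Timp1 by 1.58 and collagen I, Col1a1, by 1.49 (list adjusted p = 4.18e-26, and adjusted p = 0.0834 with an estimated correlation). Of 13 heat shock genes 8 fell (9 adjusted over the list alone), among them Hspa1a with -1.79 and Hsph1 with -1.41 (list adjusted p = 3.3e-09, and adjusted p = 0.025 with an estimated correlation). Of 22 genes of the unfolded protein response 9 fell (10 fell and 1 rose adjusted over the list alone), among them the chaperone Hspa5 with -0.81 (list adjusted p = 0.000156, and adjusted p = 0.304 with an estimated correlation). Of 38 G2 and M phase genes 18 rose (27 adjusted over the list alone), among them Aurkb by 1.54, and of 28 S phase genes 11 rose (21 adjusted over the list alone), among them Ccne2 by 1.64. Of 29 p53 targets 9 rose (11 adjusted over the list alone), with Cdkn1a at 1.33, and Ccng1 went from 9.79 ± 0.0217 to 10.99 ± 0.324 (SD, n = 3 each). These 3 lists were called higher at adjusted p = 1.53e-15, 4.74e-12 and 0.000241, with adjusted p of 0.419, 0.369 and 0.369 with an estimated correlation. Of 20 T and NK cell markers 10 fell (17 adjusted over the list alone), among them Bcl11b with -2.31 (list adjusted p = 5.52e-12, and adjusted p = 0.369 with an estimated correlation). S100a9 rose by 2.68 and S100a8 by 2.35, the macrophage gene Cd68 by 0.78, the heme oxygenase Hmox1 by 1.73 and Hbb by 2.06.

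Cop at 6 h called 1364 probe sets, 777 higher and 587 lower, in 918 genes. The T and NK cell score was -0.0487 in NMU replicate 1 and -1.18 and -1.15 in the other NMU arrays, against 0.48 to 0.887 in controls, and the skeletal muscle median was 2.36 with no marker called (list adjusted p = 0.000251, and adjusted p = 0.672 with an estimated correlation). The count was 2141 with the compared arrays alone, 834 with the muscle score and 809 with the lymphocyte score as a covariate, and 654, 670 and 732 without control replicate 1, NMU replicate 2 or NMU replicate 3. Every gene named in this paragraph and the 2 before it passed whichever array was left out. Other genes that the naming rule gave did not, among them Ccl2 and C1qb, which each lost the call without 5 of the 6 arrays.

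In Cop at 1 d, lipid synthesis genes were still lower and cell division genes had turned lower. The stearoyl-CoA desaturase Scd went from 12.45 ± 0.223 (SD, n = 3) to 9.52 ± 0.269 (n = 3), a change of -2.93 (SE 0.295, limma adjusted p = 4.2e-06), and Me1 changed by -1.87 and Acaca by -1.26. Of 23 lipid synthesis genes 4 fell (10 fell and 1 rose adjusted over the list alone; list adjusted p = 1.46e-12, and adjusted p = 0.246 with an estimated correlation). Of 38 G2 and M phase genes 10 fell, and 34 did so adjusted over the list alone, among them the proliferation marker Mki67 with -2.50 and Racgap1 with -2.35 (list adjusted p = 3.31e-33, and adjusted p = 0.196 with an estimated correlation). Of 28 S phase genes 7 fell, and 25 did so adjusted over the list alone, among them Uhrf1 with -1.54 (list adjusted p = 3.28e-24, and adjusted p = 0.149 with an estimated correlation). Cyp2e1, a cytochrome P450, rose from 5.61 ± 0.45 (SD, n = 3) to 11.33 ± 0.468 (n = 3), by 5.73 (SE 0.669, adjusted p = 3.11e-05). Of 26 interferon-stimulated genes 4 rose (12 adjusted over the list alone), among them Cxcl10 by 2.30, Cxcl11 by 1.84 and Cxcl9 by 1.48 (list adjusted p = 1.82e-15, and adjusted p = 0.181 with an estimated correlation). The protease Mmp11 rose by 2.66 and the macrophage gene Gpnmb by 1.28.

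Cop at 1 d called 158 probe sets, 85 higher and 73 lower. The count was 255 with the compared arrays alone, 360 with the lymphocyte score as a covariate, and 45, 57, 51 and 51 without control replicate 1, control replicate 2, NMU replicate 1 or NMU replicate 2. Cyp2e1, Mmp11, Gpnmb, Cxcl9, Cxcl10, Cxcl11, Scd, Me1 and Acaca passed whichever array was left out, and Mki67, Racgap1 and Uhrf1 lost their calls without at least 3 of the arrays.

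In Cop at 30 d, milk genes, lymphocyte genes and cell division genes were lower, and endothelial genes were higher. Beta casein, Csn2, went from 11.17 ± 2.41 (SD, n = 3) to 4.75 ± 1.60 (n = 3), a change of -6.43 (SE 1.77, limma adjusted p = 0.0236). Of 14 milk genes 7 fell (10 adjusted over the list alone), among them Csn1s1 with -1.56 and Lalba with -1.17, and of 23 luminal epithelial genes 5 fell (14 adjusted over the list alone), among them the alveolar regulator Elf5 with -1.61. Of 20 T and NK cell markers 11 fell (17 adjusted over the list alone), with Cd3g changed by -3.65, and of 14 B cell markers 6 fell and 1 rose (8 and 1 adjusted over the list alone), with Ms4a1 changed by -3.77. These 4 lists were called lower at camera adjusted p = 1.21e-06, 9.39e-06, 3.17e-09 and 0.000782, with adjusted p of 0.258, 0.543, 0.419 and 0.589 with an estimated correlation. Of 38 G2 and M phase genes 11 fell (19 adjusted over the list alone), among them Cks2 with -1.72, and of 28 S phase genes 13 fell (17 adjusted over the list alone), among them Pcna with -0.96. These were called lower at adjusted p = 5.13e-10 and 3.61e-10, with adjusted p of 0.543 and 0.419 with an estimated correlation. Of 15 repair genes 5 fell (7 fell and 1 rose adjusted over the list alone), among them the uracil glycosylase Ung with -1.09 and Apex1 with -0.78 (list adjusted p = 0.000627, and adjusted p = 0.258 with an estimated correlation).

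Of 14 endothelial genes in Cop at 30 d 11 rose (13 adjusted over the list alone), among them Pecam1 by 1.18 (SE 0.158, limma adjusted p = 0.000341) and Tie1 by 1.08 (list adjusted p = 2.36e-13, and adjusted p = 0.0834 with an estimated correlation). Of 26 fibroblast and matrix genes 11 rose (18 adjusted over the list alone), among them the pericyte receptor Pdgfrb by 0.91 (list adjusted p = 5.31e-09, and adjusted p = 0.371 with an estimated correlation). Of 20 macrophage genes 6 rose and 1 fell, among them the mannose receptor Mrc1 by 1.26 (list adjusted p = 0.0018, and adjusted p = 0.596 with an estimated correlation). The apolipoprotein Apod rose by 1.86 and Plin1 by 1.16.

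Cop at 30 d called 2054 probe sets, 916 higher and 1138 lower, in 1289 genes. The NMU arrays were unlike each other: the T and NK cell score was 0.629 in replicate 1 and -1.83 and -1.80 in the others, the muscle score -3.36 in replicate 1 and 1.37 and 0.532 in the others, the luminal score 0.512 in replicate 1, within the controls (0.3, 0.41 and 0.856), and 0.102 and -1.20 in the others, and the GAPDH 3 prime to 5 prime difference was highest in replicates 1 and 3 (0.358 and 0.361). With the compared arrays alone limma called 0 probe sets, with 2405 at an unadjusted p under 0.05. The count was 745 with the lymphocyte score as a covariate, 935 without NMU replicates 1 and 3 (1 NMU array left, with the spread taken from the other groups), and 1168, 3810 and 231 without control replicate 3, NMU replicate 1 or NMU replicate 3. Apod, Plin1, Pdgfrb, Pecam1, Tie1, Ung, Pcna and Cks2 passed whichever array was left out, and Csn2 lost its call without control replicate 2, control replicate 3 or NMU replicate 3. Csn1s1, Lalba, Cd3g, Apex1 and Mrc1 lost theirs without NMU replicate 3 (adjusted p = 0.0572, 0.087, 0.0927, 0.0507 and 0.098), Ms4a1 without NMU replicate 2 or 3 (0.0626 and 0.116), and Elf5 without control replicate 2 or NMU replicate 3 (0.0635 and 0.178).

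Of the 4 genes examined in every NMU comparison, Prlr (prolactin receptor) and Mgmt (repair of methylated guanine) passed in none, Cdkn1a passed at 6 h in each strain, and the clock gene Per2 passed in Cop at 30 d, with a rise of 0.82 (SE 0.255, limma adjusted p = 0.0382) that its other probe set did not share and that lost its call without any of 4 of the 6 arrays.

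**Figure D2:**
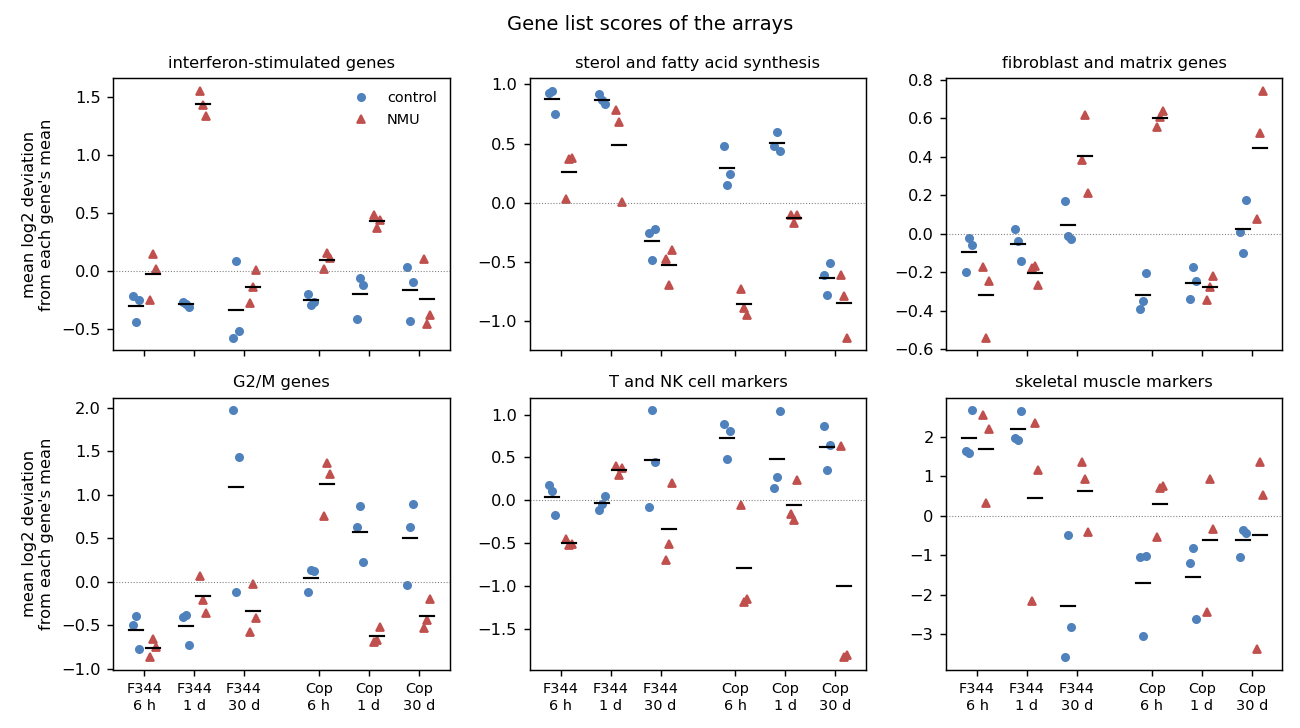
Scores of 6 gene lists on each of the 36 arrays (mean log2 deviation from each gene's mean), by strain and time, for controls (circles) and NMU (triangles), with a bar at the mean of 3 arrays. The interferon score of the F344 NMU arrays at 1 d lay between 1.33 and 1.55, above every other array, and the muscle score spread within groups.

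The strain difference in response asks whether resistant Cop glands answered NMU as susceptible F344 glands did. At 6 h, 182 probe sets differed, 141 with a higher and 41 with a lower response in Cop. Of 26 fibroblast and matrix genes 16 had the higher response in Cop (19 adjusted over the list alone; camera adjusted p = 1.4e-39, and adjusted p = 0.025 with an estimated correlation). The difference was 2.08 for Col1a1 (SE 0.253, limma adjusted p = 2.12e-05), 1.98 for Fn1 and 2.59 for Lox. Of 23 lipid synthesis genes 3 had the lower response in Cop (6 adjusted over the list alone), with -1.53 for Fasn and -1.24 for Srebf1, and of 13 heat shock genes 3 did (6 adjusted over the list alone), with -2.03 for Hspa1a. These lists were called lower at adjusted p = 7.12e-05 and 7.26e-05, with adjusted p of 0.543 and 0.149 with an estimated correlation. Of 38 G2 and M phase genes 1 passed, Aurkb, with 1.78, and 25 did so adjusted over the list alone (list adjusted p = 4.06e-23, and adjusted p = 0.301 with an estimated correlation). No p53 target differed (list adjusted p = 0.5). Skeletal muscle had a median difference of 2.59 with no marker passing (list adjusted p = 4.91e-07, and adjusted p = 0.569 with an estimated correlation). Limits are that the count was 432 with the compared arrays alone, 121 with the muscle score as a covariate, and 88, 119, 86, 103, 118 and 108 without F344 control replicate 2, F344 control replicate 3, F344 NMU replicate 2, Cop control replicate 1, Cop NMU replicate 2 or Cop NMU replicate 3. Aurkb lost its call without 10 of the 12 arrays and with the Cop replicate pairs as a block (adjusted p = 0.0604), and the other genes named passed whichever array was left out.

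At 1 d, 43 probe sets differed in response, 3 with a higher and 40 with a lower response in Cop. Of 26 interferon-stimulated genes 7 had the lower response in Cop, and 24 did so adjusted over the list alone (camera adjusted p = 5.09e-33, and adjusted p = 0.025 with an estimated correlation). The difference was -3.38 for Cxcl11 (SE 0.403, limma adjusted p = 3.8e-05), -1.59 for Irf7 and -1.25 for Oas1b, and the granzyme Gzmb differed by -2.50. Of 28 S phase genes 5 had the lower response in Cop (22 adjusted over the list alone), with -1.28 for Mcm7 (list adjusted p = 2.43e-31, and adjusted p = 0.0834 with an estimated correlation). The desaturase Scd differed by -2.72. Cyp2e1, which rose in Cop, differed by 3.79 and did not pass (adjusted p = 0.113). Skeletal muscle had a median difference of 2.83 with no marker passing (list adjusted p = 1.95e-10, and adjusted p = 0.454 with an estimated correlation). The count was 141 with the compared arrays alone, 26 with the closest pair of F344 controls averaged, 22 with the muscle and 86 with the lymphocyte score as a covariate, and 27, 22, 18, 20 and 22 without F344 control replicate 1, F344 control replicate 2, F344 NMU replicate 1, Cop control replicate 2 or Cop NMU replicate 2. The passing genes named here passed whichever array was left out.

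At 30 d, limma called 0 probe sets for the strain difference in response, with 678 at an unadjusted p under 0.05 and a smallest adjusted p of 0.387, that of Phactr1 with a difference of 1.42. The milk and bone matrix gene Spp1 differed by -1.25 and did not pass (adjusted p = 0.999). Without Cop NMU replicate 1 the count was 45, without F344 control replicate 2 it was 4 and without F344 NMU replicate 3 it was 1. Camera called lists with no member passing, among them G2 and M phase genes (median difference 0.53, adjusted p = 3.3e-07), luminal epithelium (-0.48, adjusted p = 1.45e-06), T and NK cells (-0.82, adjusted p = 2.46e-06) and skeletal muscle (-2.76, adjusted p = 4.93e-14). With an estimated correlation these were adjusted p = 0.603, 0.492, 0.543 and 0.369. No statement on which 30 d changes differ between the strains follows from these counts.

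Among 11509 genes, 23 rose and 15 fell in both strains at 6 h, against 2.67 and 0.922 expected from independent draws (Fisher's exact test, p = 2e-16 and 1.12e-15), and 3 moved in opposite directions. At 1 d, 9 rose and 0 fell in both, against 0.743 and 0.0768 expected (Fisher's exact test, p = 4.8e-08 and 1). At 30 d, 55 rose and 227 fell in both, against 3.82 and 26.7 expected (Fisher's exact test, p = 1.32e-54 and 7.01e-168), and 1 moved in opposite directions. After quantile normalization the numbers at 30 d were 126 and 242, without the filter 33 and 165, and with the stricter filter 89 and 288, and at 1 d quantile normalization gave 15 rises and 1 fall, so the number of shared rises depended on the scaling and the filter. Genes are not independent of each other, so these p-values are too small. Across genes, the correlation of the log2 changes of the strains was 0.261 at 6 h, 0.0543 at 1 d and 0.655 at 30 d, where genes are again not independent replicates.

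**Figure D3:**
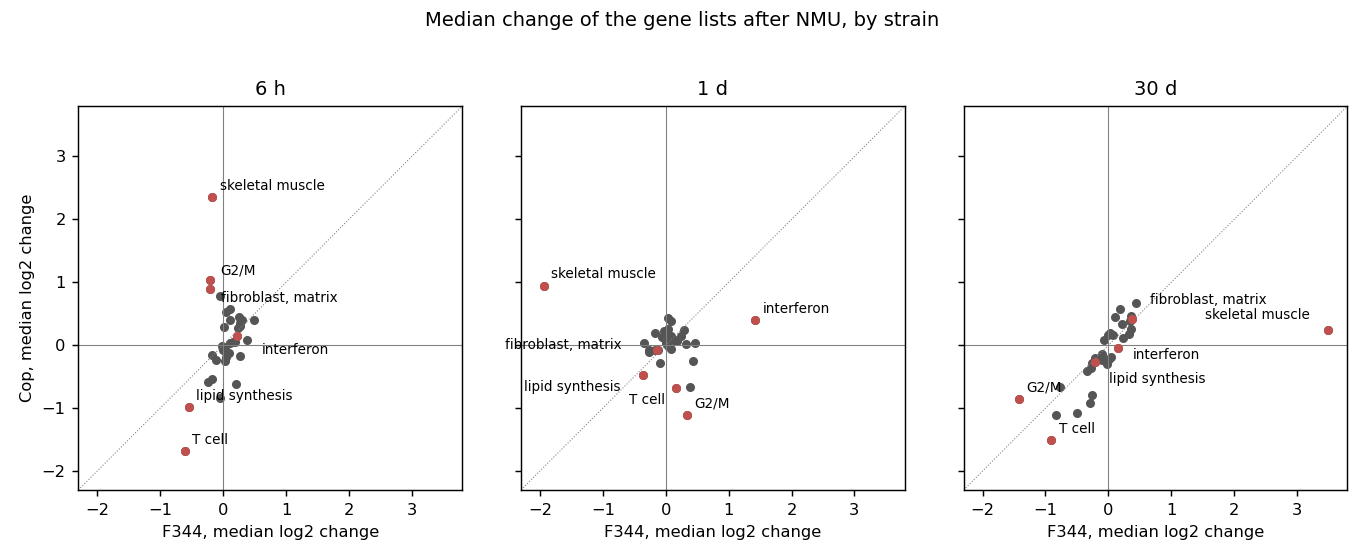
Median log2 change after NMU of each of the 34 gene lists in F344 (horizontal axis) and Cop (vertical axis) at 6 h, 1 d and 30 d, with a dotted line at equal change and named lists in red. The interferon list lies at 1.42 in F344 and 0.40 in Cop at 1 d, and the fibroblast and matrix list at -0.21 in F344 and 0.89 in Cop at 6 h.

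The comparison of control glands gives the state of the strains without the carcinogen, with 9 arrays each. The secreted iron carrier protein Lcn2 was higher in Cop, at 12.08 ± 0.471 (SD, n = 9) against 6.16 ± 0.868 (n = 9), a difference of 5.92 (SE 0.215, limma adjusted p = 6.34e-18). The cholesterol exporter Abca1 was higher by 2.67, the heparanase Hpse by 2.14 and Cyp2e1 by 2.14. Clec3b (tetranectin) was lower in Cop with -5.28 (SE 0.279, adjusted p = 8e-14), the epoxide hydrolase Ephx2 with -3.57, the imprinted RNA H19 with -3.07 and the carbonyl reductase Cbr1 with -2.58. Mgmt was lower in Cop with -0.33 (SE 0.0818, adjusted p = 0.00331). Of 29 genes of oxidative phosphorylation 27 were lower in Cop, among them Ndufs1 with -0.56, of 23 adipocyte genes 16 were lower, and of 23 lipid synthesis genes 13 were lower and 1 higher. Adjusted over the list alone, the counts were 27 lower, 19 lower and 1 higher, and 13 lower and 1 higher, and the lists were called lower at adjusted p = 4.75e-15, 1.06e-07 and 7.5e-06, with adjusted p of 0.258, 0.369 and 0.454 with an estimated correlation. Of 14 endothelial genes 8 were higher in Cop (10 adjusted over the list alone), among them Tek by 0.55, and of 20 macrophage genes 9 were higher (12 adjusted over the list alone), among them Cd68 by 0.53. These were called higher at adjusted p = 6.57e-05 and 0.00395, with adjusted p of 0.371 and 0.625 with an estimated correlation. In all 5406 probe sets differed, 2727 higher and 2679 lower in Cop. Skeletal muscle markers were lower in Cop for 14 of 26 genes (19 adjusted over the list alone, median -2.10, list adjusted p = 8.31e-08, and adjusted p = 0.543 with an estimated correlation), and the count was 3248 with the muscle score as a covariate. The comparison averages the 3 times. At 30 d the oxidative phosphorylation scores overlapped, at -0.0968, -0.366 and -0.0509 in F344 and -0.294, -0.133 and -0.17 in Cop. Adipocyte scores also overlapped then. So did muscle scores, at -3.58, -0.495 and -2.80 in F344 and -1.04, -0.358 and -0.427 in Cop. The differences in these lists lay mostly at the earlier times.

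The change of controls with time gives the background to the times after treatment. Between 6 h and 1 d, 38 probe sets changed, 21 higher and 17 lower at 1 d, among them the clock genes Nr1d1 by 1.40 (SE 0.152, limma adjusted p = 6.9e-06) and Dbp by 1.07, while the aldehyde oxidase Aox1 fell from 8.71 ± 0.237 to 7.71 ± 0.798 (SD, n = 6 each). These 3 passed whichever array was left out. The count was 67 after quantile normalization, 23 without the filter, 122 with the compared arrays alone, 7 with the closest pair averaged, and from 6 to 64 when single arrays were left out. Those counts were 12, 6 and 12 without F344 control replicates 1, 2 and 3 of 6 h, 18 and 7 without Cop control replicates 1 and 2 of 6 h, 7, 7 and 64 without F344 control replicates 1, 2 and 3 of 1 d, and 7, 10 and 20 without Cop control replicates 1, 2 and 3 of 1 d.

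At 30 d against both earlier times, 6244 probe sets differed in controls, 2847 higher and 3397 lower. Lipid synthesis genes were lower for 19 of 23, with Elovl6 at 6.73 ± 0.503 (SD, n = 6) against 10.20 ± 1.00 (n = 12), a change of -3.47 (SE 0.245, limma adjusted p = 4.44e-11), and the lipid droplet gene Pnpla3 changed by -4.02. Of 23 adipocyte genes 17 were lower, and of 29 oxidative phosphorylation genes 24 were lower (26 adjusted over the list alone). These 3 lists were called lower at adjusted p = 1.01e-16, 8.21e-10 and 5.91e-14, with adjusted p of 0.149, 0.258 and 0.294 with an estimated correlation. Of 38 G2 and M phase genes 35 were higher, with Stmn1 by 1.12, of 23 luminal epithelial genes 19 were higher (20 adjusted over the list alone), with Elf5 by 1.38, and of 22 prolactin and Stat5 pathway genes 13 were higher and 1 lower (15 and 2 adjusted over the list alone), with Stat5a by 0.73. These 3 lists were called higher at adjusted p = 5.1e-14, 7.87e-08 and 0.00058, with adjusted p of 0.448, 0.426 and 0.0834 with an estimated correlation. The neuronal imprinted gene Nnat rose by 3.32 (SE 0.465, limma adjusted p = 6.82e-06) and Slc34a2 by 2.39. Skeletal muscle markers were lower for 6 of 26 genes (2 adjusted over the list alone, median -1.96, list adjusted p = 0.000463, and adjusted p = 0.672 with an estimated correlation). These values average the strains. The G2/M score of F344 controls was 1.97, -0.116 and 1.43 at 30 d against -0.774 to -0.379 earlier. In Cop controls it was -0.0349, 0.633 and 0.896 against -0.113 to 0.871, so the rise lay mostly in F344. The luminal score of F344 controls was 0.584, 0.671 and 0.545 at 30 d against -0.757 to -0.41 earlier. In Cop controls it was 0.3, 0.41 and 0.856 against -0.00383 to 0.359, so this rise also lay mostly in F344. Prolactin and Stat5 scores at 30 d were 0.458, 0.514 and 0.459 in F344 (earlier -0.443 to -0.232). In Cop they were 0.317, 0.105 and 0.336 (earlier -0.0228 to 0.132). The muscle score of Cop controls was -1.04, -0.358 and -0.427 at 30 d against -3.04 to -0.813 earlier, so its fall lay in F344. Oxidative phosphorylation scores of Cop controls at 30 d (-0.294, -0.133 and -0.17) overlapped the earlier ones (-0.277 to 0.243).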

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

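The tests of explanations in this part, the regroupings of arrays among them, were all chosen after the results were seen, while the strain differences in response were fixed before. A difference between the strains in the response to NMU was found by the test of the difference itself. Values are Cop response minus F344 response on the log2 scale.

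At 6 h, 182 probe sets differed. The genes of largest difference were Cgref1 (2.96), Aldh1l2 (2.88), Lox (2.59), Cdh22 (2.45) and C1qtnf6 (2.41), and in the other direction Angptl8 (-3.37), Hspa1a (-2.03), Slc22a3 (-1.82), Tmeff1 (-1.63) and Rasd1 (-1.60). Angptl8 lost its call without 9 of the 12 arrays and with the Cop replicate pairs as a block (adjusted p = 0.0667), Tmeff1 without 4 and Cdh22 without 3. Lists with members that differed had median differences of 1.11 (fibroblast and matrix), 1.29 (G2/M), 0.479 (S phase), 0.918 (erythroid), -0.591 (adipocyte), -0.422 (lipid synthesis) and -0.351 (heat shock). Of these list calls only that of the fibroblast and matrix list held with an estimated correlation. The only erythroid gene to pass, Hbb (adjusted p = 0.044), lost its call without 11 of the 12 arrays, the only S phase gene, Uhrf1 (adjusted p = 0.047), without 9, and the only G2/M gene, Aurkb, without 10.

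At 1 d, 43 probe sets differed. The genes of largest difference were Pamr1 (1.91), Slc35e4 (0.86), Pclaf (-3.39), Cxcl11 (-3.38), Scd (-2.72), Gzmb (-2.50) and Uhrf1 (-2.31). Pamr1 lost its call without 3 of the 12 arrays, Slc35e4 without 7, Pclaf without 1 and Uhrf1 without 4. Median differences were -1.07 (interferon), -0.935 (S phase), -1.47 (G2/M) and -0.916 (T and NK cell). Of these list calls only that of the interferon list held with an estimated correlation. The 2 G2/M genes to pass, Stmn1 and Cks2 (adjusted p = 0.0459 and 0.0486), each lost the call without 11 of the 12 arrays, and of the T and NK cell genes Gzmb alone passed, with Gzma at adjusted p = 0.133.

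Other groupings of the same arrays were fitted, and where more than 100 exist the number drawn was raised to 100 after a smaller first draw had been seen. Numbers of splits include the real grouping. For each NMU comparison within a strain there are 10 splits of the 6 arrays, too few for a share under 0.05. Real counts against the highest other split were 129 against 2, 204 against 1 and 683 against 93 in F344 at 6 h, 1 d and 30 d, and 1364 against 5, 158 against 1 and 2054 against 1862 in Cop. In Cop at 6 h and 1 d, where arrays of the same number deviated together, the 3 other splits that part every same-numbered pair called 0 by limma. Those that part a single pair called at most 5 and 1. Whether the numbers mark true pairs was not tested. The 1862 came from exchanging Cop NMU replicate 1 with Cop control replicate 2. For the strain difference in response, 7 of 100 splits gave as many as the 182 at 6 h (highest other 1413) and 11 of 100 as many as the 43 at 1 d (highest other 402), so chance is not excluded by this count. These splits shuffle treatment within each strain, which also breaks the response that the strains share. The shares are therefore not a test of no strain difference alone. At 30 d the real count of 0 by limma (678 at an unadjusted p under 0.05) is reached by any split, 100 of 100 (highest other 4363), so the count decides nothing there. In each of the 3 highest splits all 6 Cop arrays were relabelled, which adds the responses of the strains in place of subtracting them, a structure of the samples. For Cop against F344 (5406, 1 of 100 splits as large, highest other 4018) and 30 d against earlier (6244, 1 of 100, highest other 1547), only the real grouping called as many. This argues against chance, provided the arrays are separate animals. For 1 d against 6 h, 4 of 100 splits called as many as the 38, and the highest other called 853, which points to a structure of the samples. That count was also 6 without F344 control replicate 2 of 6 h and 7 with the closest pair averaged, so it is not taken as firm.

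Far more probe sets were called in Cop than in F344 at 6 h, with lipid synthesis genes lower. More muscle in an arm is argued against as the whole cause, since with the muscle score as a covariate 59.2% of the calls held in the same direction. A loss of adipocytes may account for a part. The 20 adipocyte markers that are not lipid synthesis genes had a median change of -0.203, with 6 called lower and 0 higher, against -0.979 for the lipid synthesis list. The bootstrap 95% interval of the -0.203, from -0.598 to -0.0166, resampled genes and not arrays. These tests cannot tell how much of the fall was regulation. A gland state like that of later collection also stays open, since the Cop change at 6 h correlated with the change of F344 controls to 30 d across the 918 genes called (r = 0.32) and not across all genes (r = -0.146), with 54.5% of the genes of the same sign. The strain difference in response at 6 h was tested and passed for 3 of 23 lipid synthesis genes, and what underlies it stays open, feeding state among others.

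Lymphocyte genes were lower after NMU in Cop at 30 d, in NMU replicates 2 and 3 but not in replicate 1 (T and NK cell score 0.629 against 0.868, 0.35 and 0.642 in controls), and neither list call held with an estimated correlation (adjusted p = 0.419 for T and NK cells and 0.589 for B cells). Dilution of all other cell types by fat and vessels is argued against only across the genes of the lists. T cell genes were lower than basal epithelial genes by a median difference of -1.21 (bootstrap 95% interval -1.97 to -0.634). That bootstrap resampled genes and not arrays, so the interval does not measure the spread between glands. Less lymph node tissue in the NMU glands stays open: 3 node stroma genes had a median of -1.64 (Ccl19 -2.09, Ccl21 -1.65 and Cxcl13 0.25), against -1.51 for T cell and -1.08 for B cell genes. Ccl19 and Ccl21 were called lower (adjusted p = 0.025 and 0.0217) and Cxcl13 was not called (0.687), too few genes to decide, and the labels do not describe how the gland was sampled. The node genes Glycam1 and Ltb were left out of that median, as genes also made by milk cells or lymphocytes. Both were called lower as well, with -4.11 and -2.23 (limma adjusted p = 0.00606 and 0.0242). A loss of lymphocytes after NMU stays open and was not tested.

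In the control glands 5406 probe sets differed between the strains. Strain variants under the probes are argued against for called genes with a log2 difference over 1 and a further probe set, since 58 of 60 such genes (96.7%, Wilson 95% interval 88.6 to 99.1) changed the same way on their other probe sets, with a median ratio of changes of 0.793. Genes of smaller difference, and genes read by a single probe set such as Lcn2, were not covered by that test. More muscle in the F344 glands is argued against as the whole cause, since 57.2% of the calls held in the same direction with the muscle score as a covariate. Inherited differences in expression stay open and were not separated from differences in cell content.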

How the results depend on the processing

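The muscle and lymphocyte covariates, the averaged pair, the block of Cop pairs and the exclusion by GAPDH difference were chosen after the data were seen; the other alternatives were planned. None of the named genes followed through the alternatives reversed a call, and none of the called lists did under the alternatives run for lists. Reversals had little room to arise. Many named genes were picked because they were called in these data, and a list counted as reversed only if called in both settings. Other called probe sets were not followed singly. Total counts that moved by over 1.5 times were these, and the cause was not tested except where fewer arrays or genes were used by construction. Quantile normalization gave 67 for 1 d against 6 h and an overlap of 16 genes at 1 d. No filter gave 85 for F344 at 6 h and 23 for 1 d against 6 h. The compared arrays alone gave 7 and 2 for F344 at 6 h and 30 d, 2141, 255 and 0 for Cop at 6 h, 1 d and 30 d (2405 at an unadjusted p under 0.05 by limma), 432 and 141 for the strain difference at 6 h and 1 d, and 122 for 1 d against 6 h. The muscle score gave 13 for F344 at 30 d, 834 for Cop at 6 h, 121 and 22 for the strain difference at 6 h and 1 d, and 3248 for Cop against F344. At F344 30 d the median size of the called changes went from 0.632 to 0.557 and the median SE from 0.152 to 0.169, with 100% of signs unchanged. The lymphocyte score gave 342 for F344 at 6 h, 809, 360 and 745 for Cop at 6 h, 1 d and 30 d, and 86 for the strain difference at 1 d. The averaged pair gave 26 for the strain difference at 1 d and 7 for 1 d against 6 h. Without Cop NMU replicates 1 and 3, which left 1 NMU array and took its spread from the other groups, Cop at 30 d gave 935, and of its named genes 44 calls ended, 4 were gained and 53 stayed on their side. A floor at the 20th percentile, a stricter filter and plain empirical Bayes moved no total that far. In a single direction, with the total moved less, quantile normalization moved the falls of F344 at 6 h from 51 to 84, its rises at 30 d from 138 to 286, the shared falls at 6 h from 15 to 23 and the shared rises at 30 d from 55 to 126, which were 33 without the filter and 89 with the stricter one. Plain empirical Bayes moved the falls of 1 d against 6 h from 17 to 11, the averaged pair the falls of F344 at 1 d from 36 to 15, and the lymphocyte score the strain difference at 6 h from 141 to 92 higher and the falls of 1 d against 6 h from 17 to 27.

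The replicate number as a block over all arrays gave 19 for 1 d against 6 h, and 30 calls of named genes ended under it. Outside Cop at 6 h and 1 d the numbers were not taken as pairs, since at least 1 pair of each other NMU comparison correlated below 0.1 (over all NMU comparisons 10 of 18 above, range -0.351 to 0.507, 9 of 18 best with their own number). A block of the pairs in Cop at 6 h and 1 d gave 1352 and 146, and 153 and 34 for the strain difference at 6 h and 1 d, with 11 calls of named genes and 1 list call ended and 2 gained among named genes.

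Leaving out single arrays gave 23 to 136, 137 to 304 and 29 to 1109 for F344 at 6 h, 1 d and 30 d, and 654 to 1158, 45 to 151 and 231 to 3810 for Cop. The strain difference ranged from 86 to 196, 18 to 48 and 0 to 45 (limma; 678 at an unadjusted p under 0.05 with all arrays), Cop against F344 from 4633 to 5491, 1 d against 6 h from 6 to 64, and 30 d against earlier from 4976 to 6565. Where a group was left with 2 arrays, these were assumed to vary like the other groups. Among named genes 895 calls were lost and 82 gained over all single exclusions, against 9679 on the same side of the threshold. Of 173 list calls, 168 were lost with an estimated correlation, 10 after quantile normalization, 8 without the filter and 3 with the mean of a gene's probe sets. Signal near background limits dim genes, which the filter leaves out.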

Other observations

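The test of a hypothesis in this part was chosen after the result was seen; the gene lists were fixed before. Clock genes differed between the groups. In control glands Dbp and Nr1d1 were lower in Cop than in F344 (-1.15 and -1.06) and Bmal1 was higher (0.73), and of 18 clock genes 3 were higher and 8 lower (3 and 11 adjusted over the list alone; camera adjusted p = 0.00695, and adjusted p = 0.426 with an estimated correlation). In Cop at 6 h after NMU, Dbp rose by 1.24, Nr1d1 by 1.17 and Per3 by 0.90, while Bmal1 changed by -0.85 (4 higher and 1 lower of 18, list not called, adjusted p = 0.0852). In Cop at 30 d Per3 rose by 0.98 and Bmal1 changed by -0.82. Bmal1 lost its call at 6 h without control replicate 2, NMU replicate 2 or NMU replicate 3 (adjusted p = 0.0549, 0.0537 and 0.0565), and at 30 d without NMU replicate 3 (adjusted p = 0.163). The labels do not give the time of day of collection.

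Some nerve sheath genes and 2 mast cell genes were higher in Cop at 30 d after NMU. Of 10 nerve and Schwann cell genes 4 rose, among them the myelin gene Mbp by 1.46, a rise that 1 of its 2 other probe sets shared, and Pllp by 1.00 (4 higher and 1 lower adjusted over the list alone; list adjusted p = 0.00529, and adjusted p = 0.196 with an estimated correlation). Of 10 neutrophil and mast cell genes 2 rose, the mast cell genes Ms4a2 by 0.69 and Cma1 by 0.96 (6 adjusted over the list alone; list adjusted p = 0.00884, and adjusted p = 0.543 with an estimated correlation). The neutrophil and mast cell score of NMU replicate 2 (-0.223) lay inside the controls (-0.17, -0.687 and 0.00914). Mbp and Pllp passed whichever array was left out, while Ms4a2 lost its call without 2 arrays and Cma1 without 4. In control glands the same mast cell gene Ms4a2 changed by -0.66 from the earlier times to 30 d, with Cpa3 at -0.87. Between the control strains, the prolactin and Stat5 pathway list was not called (5 of 22 higher and 2 lower in Cop, adjusted p = 0.457, and adjusted p = 0.709 with an estimated correlation), with Ccnd1 higher in Cop by 1.23 and the receptor Ghr lower with -0.98. The estrogen and progesterone response list had no called member in any NMU comparison, and the apoptosis list had 1 in Cop at 6 h and 1 in Cop at 30 d.

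Cell division genes were lower 30 d after NMU in both strains. Over the strains together, both they and luminal genes were higher in controls at 30 d than earlier. None of these list calls held with an estimated correlation. Both comparisons use the same 30 d controls, so controls that were high by themselves would give both. The G2/M rise of controls lay mostly in F344 replicates 1 and 3 (scores 1.97 and 1.43). The luminal rise of controls also lay mostly in F344 (0.545 to 0.671 at 30 d against -0.757 to -0.41 earlier). The luminal list was called lower after NMU in Cop, but not with an estimated correlation (adjusted p = 0.543), with replicate 1 within the controls (0.512) and replicate 3 the lowest (-1.20). It was not called in F344 (1 of 23 lower, camera adjusted p = 0.254). A hypothesis is that NMU slowed the change of the gland with age. In Cop the NMU change at 30 d ran against the change of F344 controls to 30 d, as slowing would give. The correlation was r = -0.586 across called genes, with 67.9% of opposite sign, and r = -0.35 across all genes. It cannot tell slowing from a difference in cell content, since the F344 control change includes the luminal and G2/M rises and NMU replicate 3 had a low luminal score. Lipid synthesis scores did not go with slowing. In Cop at 30 d they were -0.609, -0.784 and -1.14 after NMU and -0.608, -0.781 and -0.508 in controls. Earlier Cop controls scored 0.149 to 0.595, so these values argue against a slowing of all age changes in Cop. The G2/M scores after NMU (-0.534, -0.443 and -0.199) lay below every earlier Cop control (lowest -0.113). In F344 the values against the change of Cop controls decided nothing (r = -0.127 across called genes, 37.5% of opposite sign; r = 0.185 across all genes). The age changes of the strains' controls correlated at r = 0.346, and genes are not independent replicates. The difference between the strains in r was not tested, and the strain difference in response at 30 d, which was, called 0 probe sets by limma (678 at an unadjusted p under 0.05) and no list with an estimated correlation (luminal adjusted p = 0.492, G2/M adjusted p = 0.603).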
